A study of Mus musculus with 6 samples.

How the data were processed

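Liver RNA from 6 mouse samples, 3 wildtype and 3 deficient in Ugcg, was labelled with biotin as cRNA and hybridised to Affymetrix arrays, per the labels' protocols. The labels do not say whether each sample came from a separate animal, so p-values measure the spread between these samples, which may be technical. The deposited table holds log2 expression values, as read from its values: they run from 5.38 to 14.69, and the brightest reading of a 16-bit scanner is 16 in log2 but 11.1 in natural log and 4.82 in log10. The array type, background correction, normalization, summarisation and software used by the authors are not given in the sources used here. Array medians differed by at most 0.0190, and the values were used as deposited. Of 16395 probe sets, 64 were the manufacturer's AFFX controls, which were left out of all tests. The other 16331 were each named by 1 Entrez gene number, which shows that probes were grouped into 1 set per gene, so that a value averages over whatever parts of a transcript its probes read. The annotation gave 1 symbol for 15644 probe sets, several for 0 and none for 687. Of the named probe sets, 15617 matched the reference gene table of assembly GRCm38.p6, and 0 symbols changed. That table served for names and for the order of genes along the chromosome; no genome build goes with the deposited table, so no coordinates are given. No detection calls were used, and the number of arrays limits the precision.

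Groups were taken from the sample labels. Knockout was compared with wildtype by limma (version 3.58.1, R 4.3.3) with lmFit and eBayes, with 4 residual and 4.85 prior degrees of freedom, two-sided, with Benjamini-Hochberg adjustment over all probe sets except controls, and again over the named genes. The threshold was an adjusted p under 0.05. An exact permutation test of 3 against 3 arrays cannot go below p = 0.1 and was used only for scores of single gene groups. The gene lists (36 lists, 755 genes, of which 655 had a probe set used here) were tested by camera with a correlation preset at 0.01, with an estimated correlation and fry as alternatives, and adjusted over the lists. Genes beside Ugcg were compared with all other genes that have a position by Fisher's exact test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

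The genes named in the Results follow a rule written before the data were examined, except Cela2a, Prss2 and Ptf1a of the pancreas list. The closing sections name further genes outside this rule. Ugcg was named first. Genes past the threshold whose groups do not overlap came next; because fewer than 5 passed in each direction, the 10 genes per direction with the smallest p whose groups do not overlap were named in their place, and those that did not pass are said not to have passed. For each list that passed, or had a member past the threshold over the list alone, up to 4 members with the smallest p were named, and for other lists up to 2 members with the highest mean; for some of these other lists no member is given. Predicted genes with no proper name were counted and not named.

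The alternatives were quantile normalization, median centring, leaving out probe sets at or below the 40th percentile of the mean, an intensity trend with robust variance, array quality weights, other thresholds, other widths of the neighbourhood, and leaving out each array in turn. Leaving out wildtype 430 and knockout 427 together was added after the data were seen. The limma and camera steps were tested on simulated data with the 16331 probe sets and 3 against 3 arrays, in 10 draws with 200 changed probe sets. They recovered 63.4% of probe sets changed by 0.5 on the log2 scale, 97.8% of those changed by 1 and 99.8% of those changed by 2, and 4.45% of all calls were false. These rates depend on the 200 changed probe sets, because the Benjamini-Hochberg cutoff is stricter when fewer probe sets change. The real arrays gave 4 probe sets past the threshold, and Foxq1, which differed by -1.24, was not among them. The recovery rates therefore do not carry over to the real comparison. Of lists with no change 0% were called, and a list moved by 0.3 was called in 10 of 10 draws. Each simulated gene was drawn independently, so these list rates do not hold for lists whose genes move together. In the real data the estimated correlation reached 0.807 for the pancreas list. All 10 splits of the real arrays into 3 and 3 called at least 2 lists.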

Results

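Gene expression was measured with Affymetrix arrays in 6 mouse liver samples, of which 3 were labelled wildtype (arrays 426, 428 and 430) and 3 were labelled deficient in Ugcg (arrays 427, 429 and 431, called knockout arrays after that label). Ugcg encodes UDP-glucose ceramide glucosyltransferase, the enzyme that adds glucose to ceramide and thereby starts the synthesis of the glucosylceramide-based glycosphingolipids of cell membranes. The table gave 1 log2 expression value per array for each of 16331 gene probe sets, of which 15644 carried a gene symbol. Array medians lay between 6.79 and 6.81. The correlation across probe sets between pairs of arrays ran from 0.988 to 0.994, with a mean of 0.991 over the 6 pairs within a genotype and 0.991 over the 9 pairs across genotypes; probe sets are not independent replicates. The first principal component held 31.5% of the variance and set knockout 427 (-11.9) and wildtype 430 (-14.5) apart from the other arrays (3.69 to 9.44). With 3 arrays per group, the median standard error of a difference was 0.0847 on the log2 scale, and the 95% interval of a difference reached 0.192 to either side at the median. All differences are knockout minus wildtype on the log2 scale.

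The first comparison asked whether the transcript of the deleted gene was lower in the knockout arrays. Ugcg (Entrez gene 22234) had a mean of 6.84 ± 0.03 on the wildtype and 6.83 ± 0.25 on the knockout arrays (SD, n = 3 each). The wildtype arrays read 6.81, 6.85 and 6.87. Knockout 427 read 7.12, above all wildtype arrays, whereas knockout 429 at 6.70 and knockout 431 at 6.68 lay below them. The group means differed by -0.00879 (SE 0.117, 95% interval -0.274 to 0.256, limma adjusted p = 0.998). The difference was -0.154 without knockout 427, and it was above 0 without wildtype 430 (0.00326), knockout 429 (0.0602) or knockout 431 (0.0675). The positions of the array's probes and of the deleted exons are not given in the sources used here, so this probe set does not check the genotype labels, and every direction given for the knockout arrays rests on those labels.

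The main comparison asked which genes differed between the arrays labelled deficient in Ugcg and those labelled wildtype. In the knockout arrays G6pc and Rnf145 were higher, and Ndufs5 and Cish were lower; these were the 4 probe sets past the threshold. G6pc, the catalytic subunit of glucose-6-phosphatase that releases free glucose in the last step of gluconeogenesis, rose 1.91-fold, from 11.72 ± 0.14 to 12.66 ± 0.09 (SD, n = 3 each). Rnf145, a ubiquitin ligase of the endoplasmic reticulum membrane, rose 1.81-fold, from 8.49 ± 0.16 to 9.35 ± 0.11 (SD, n = 3 each). Ndufs5, a subunit of mitochondrial respiratory complex I, fell by 0.80 on the log2 scale, and Cish, a feedback inhibitor of cytokine receptors that STAT5 induces, fell by 1.29.

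**Figure D1:**
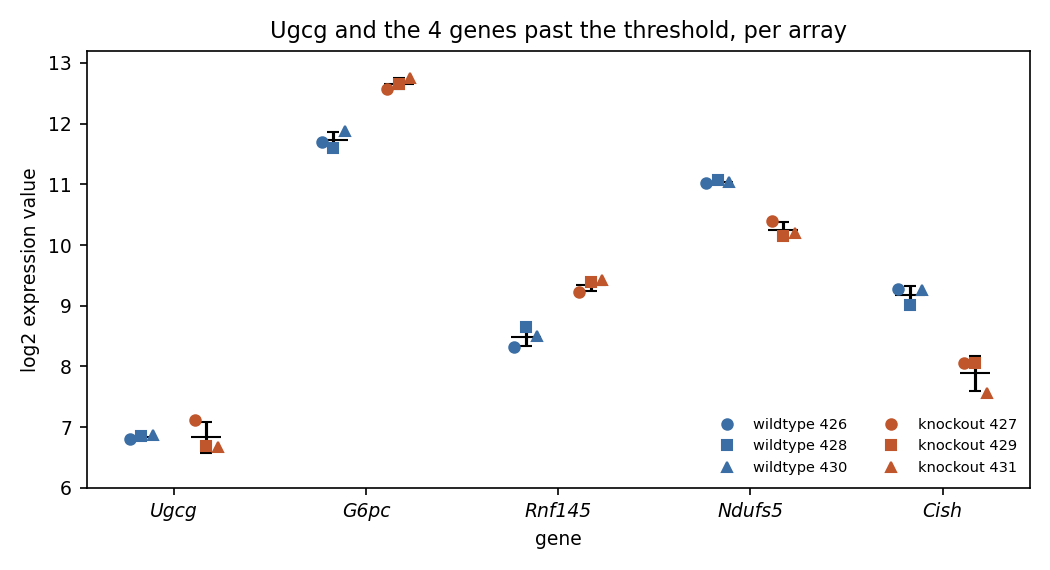
Log2 expression values of Ugcg and of the 4 genes past the threshold on each of the 6 arrays, with wildtype in blue, knockout in orange, and black lines for the group mean with 1 SD either way (n = 3). G6pc (11.72 against 12.66) and Rnf145 were higher on each knockout array than on any wildtype array, Ndufs5 and Cish were lower, and the Ugcg values of the groups overlapped.

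In the limma fit with Benjamini-Hochberg adjustment over the 15644 named genes, the adjusted p was 0.0363 for G6pc (SE 0.0900), 0.0463 for Rnf145 (SE 0.0979), 0.0363 for Ndufs5 (SE 0.0810) and 0.0422 for Cish (SE 0.140). Of the 16331 probe sets, 2 rose and 2 fell at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 815 (431 higher and 384 lower), against 817 that would be reached with no effect. The values of the groups did not overlap for 1563 probe sets, or 9.57%, where chance gives 10%. No probe set passed when wildtype 426, wildtype 428, knockout 427, knockout 429 or knockout 431 was left out of the limma fit, with 584 to 1022 at an unadjusted p under 0.05 (Ndufs5 passed among named genes alone without knockout 427). Without wildtype 430, whose pancreatic transcripts are described with the gene groups, 4 passed, of which G6pc was the gene shared with the full set of arrays, and without both wildtype 430 and knockout 427, 8 passed, with G6pc and Ndufs5 shared.

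**Figure D2:**
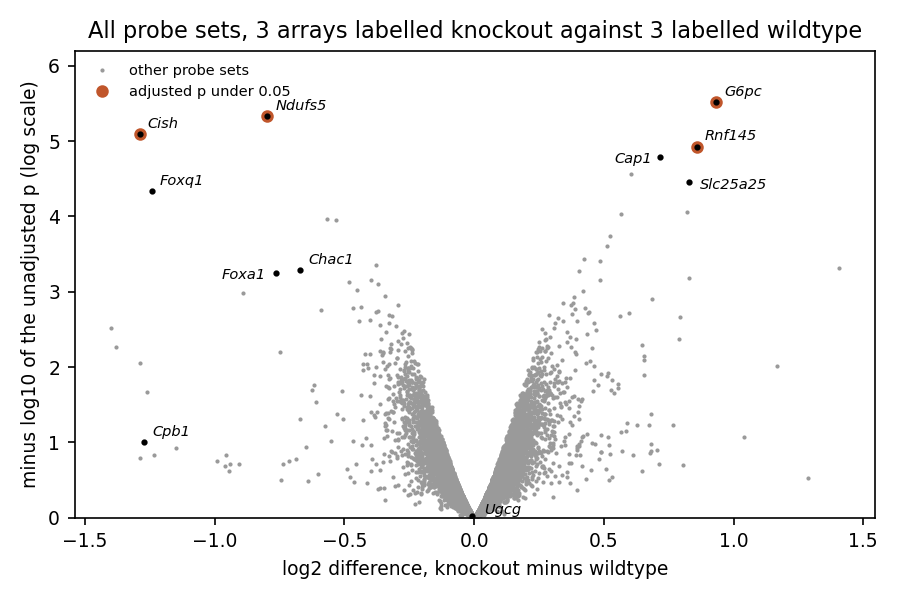
Log2 difference (knockout minus wildtype, horizontal axis) and minus log10 of the unadjusted limma p (vertical axis) for 16331 probe sets, with the 4 probe sets at an adjusted p under 0.05 in orange and other labelled genes in black. Ugcg lies at -0.00879, and the pancreatic gene Cpb1 lies far to the left at a high p.

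Since 2 genes passed in each direction, the 10 named-gene places per direction were filled with the smallest p-values among genes whose groups did not overlap; the genes that follow did not pass. On the higher side these were Cap1, an actin-binding protein (0.72, adjusted p = 0.0509), Pik3r4, the regulatory subunit of the class III phosphatidylinositol 3-kinase (0.61, adjusted p = 0.0705), and Slc25a25, a mitochondrial ATP-magnesium/phosphate carrier (0.83, adjusted p = 0.0790). The co-chaperone Dnajb4 (0.57), Ccdc68 (0.52), Acpp (0.51), Ifrd2 (0.42) and a gene with no proper name came after them, at adjusted p-values from 0.146 to 0.376. On the lower side the forkhead factor Foxq1 differed by -1.24 (adjusted p = 0.0903). Gpcpd1, which splits glycerophosphocholine (-0.57), Crebrf (-0.53) and Tex12 (-0.38) followed at adjusted p-values from 0.147 to 0.408. Chac1, a glutathione-degrading enzyme of the ATF4 response (-0.67), and Foxa1, a transcription factor of hepatocyte differentiation (-0.76), both had an adjusted p of 0.416, and Fnip1 (-0.40) and Tcta (-0.48) one of 0.477. Cap1, Pik3r4, Slc25a25 and Foxq1 passed with an intensity trend and robust variance and with array quality weights, Chac1 (-0.83) and Foxq1 (-1.44) passed without wildtype 430, and Slc25a25 (1.005), Foxq1 (-1.36) and Chac1 (-0.86) passed without both wildtype 430 and knockout 427. Over the 12 refits the limma adjusted p ran from 0.0366 to 0.262 for Cap1, 0.0468 to 0.294 for Pik3r4, 0.0135 to 0.377 for Slc25a25, 0.0135 to 0.354 for Foxq1 and 0.0245 to 0.994 for Chac1.

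Of 36 gene lists fixed before the data were examined, 2 passed limma's camera test with a preset correlation of 0.01, pancreatic genes and genes of p53 and apoptosis, and both were lower in the knockout arrays. Neither held with an estimated correlation (adjusted p = 0.763 for each list). Of 12 measured pancreatic genes, 11 were lower, with a mean difference of -0.86 and a median of -0.93 (camera adjusted p = 0.000620 with the preset and 0.763 with an estimated correlation). All 11 measured genes of the exocrine pancreas, which make digestive enzymes and colipase, had their highest value in wildtype 430, and 10 of them lay at least 2-fold above the mean of the other 5 arrays. The elastase gene Cela2a was 13.4-fold higher there, the carboxypeptidase gene Cpa1 11.3-fold and the trypsinogen gene Prss2 7.91-fold, whereas the pancreatic transcription factor Ptf1a differed by -0.0002 from the mean of the others. Cpb1 (-1.27), Ctrl (-1.15), Cela1 (-0.35) and Cpa1 (-1.23) had the smallest p-values of the list, and no member passed over the list alone or over all genes. Without wildtype 430 the mean difference of the list was -0.0338 (adjusted p = 0.405).

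**Figure D3:**
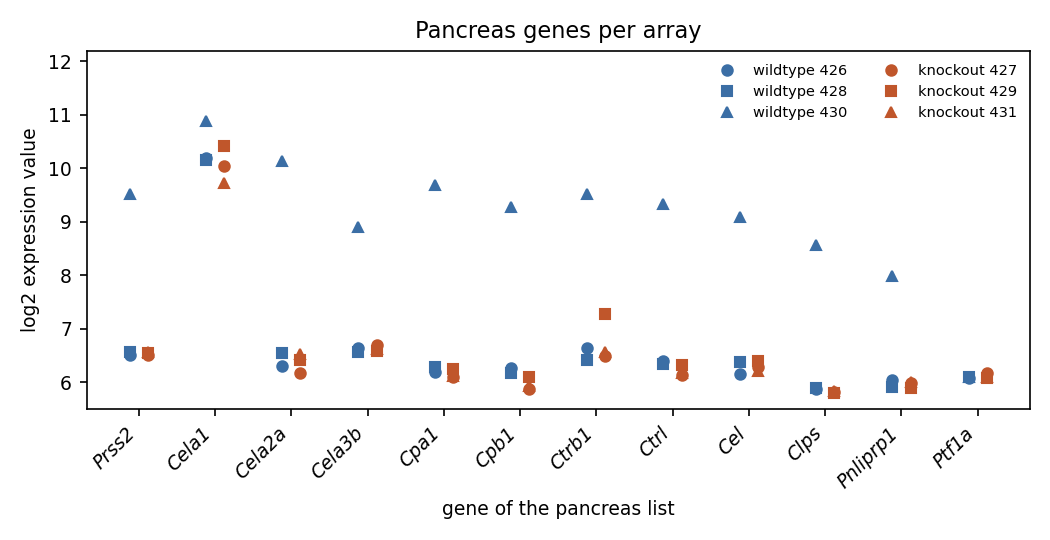
Log2 expression values of the 12 measured genes of the pancreas list on each of the 6 arrays, with wildtype in blue and knockout in orange. The triangle of wildtype 430 is the highest point for the first 11 genes, among them Cela2a at 10.13, and Ptf1a lies near 6.1 on every array.

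Of 20 measured genes of p53 and apoptosis, 15 were lower and 5 higher, with a mean difference of -0.0965 and a median of -0.0854 (camera adjusted p = 0.0166 with the preset and 0.763 with an estimated correlation). Cdkn1a, an inhibitor of cyclin-dependent kinases, differed by -0.59 and passed the limma test adjusted over the list alone (adjusted p = 0.0347) but not over all genes (0.654). The proapoptotic Bbc3 (-0.36), the stress-response gene Sesn1 (-0.22) and the growth-arrest gene Gadd45a (-0.29) passed neither. Neither list passed fry, the rotation test of whether a list moves one way (adjusted p = 0.814 for pancreas and 0.785 for p53 and apoptosis). The p53 list also lost its call without wildtype 428 (-0.0662, adjusted p = 0.104) or knockout 431 (-0.0957, adjusted p = 0.0780). Relative to the wildtype mean, the list mean of wildtype 430 (-0.0815) lay below that of knockout 427 (-0.0770), so the groups overlapped.

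The remaining 34 lists did not pass camera (adjusted p from 0.0531 to 0.838), although 17 of them passed with the preset correlation when 1 array or another was left out; with all arrays none passed with an estimated correlation or by fry's test for movement one way. Leaving out 1 array turned the sign of the mean difference for 17 of the 36 lists. Of the 34 lists, 5 had 1 member that passed adjusted over the list alone. Of the 45 list members named by the rule beside the 19 genes with the smallest p, 31 had a difference that moved by over 1.5 times when 1 array was left out. For insulin signalling and glucose metabolism (13 members higher, 10 lower, adjusted p = 0.201) this was G6pc. Tat, which starts tyrosine breakdown (0.43), and Pck1, which makes phosphoenolpyruvate for gluconeogenesis (0.38), had positive differences, and the coactivator Ppargc1a had one of -0.33; none of these passed. This list alone passed fry's test for change in either direction (adjusted p = 0.00201), but it passed neither camera with an estimated correlation (adjusted p = 0.763) nor fry's test for movement one way (adjusted p = 0.615). The list holds G6pc, which had the smallest limma p of all probe sets, and fry was not run without it. For ER stress (15 higher, 7 lower, adjusted p = 0.154) the member was Chac1 (0.0113 over the list alone), beside asparagine synthetase Asns (1.17), Ddit3 (0.32) and Dnajb9 (0.30, and 0.11 without knockout 431). For hepatocyte identity (9 higher, 11 lower, adjusted p = 0.209) it was Foxa1 (0.0112 over the list alone), beside Foxa2 (-0.61), Cebpa (-0.18) and Tdo2 (-0.11). For the cell cycle (14 higher, 10 lower, adjusted p = 0.440) it was the G1 cyclin gene Ccnd1 (0.60, 0.0458 over the list alone), beside Rrm2 (-0.42), Bub1 (0.16) and Ccnb2 (-0.13). For pericentral hepatocyte genes (8 higher, 8 lower, adjusted p = 0.830) it was Tbx3 (0.68, 0.0200 over the list alone), beside Oat (0.39), Aldh1a1 (-0.19) and Slc13a3 (0.29); the mean of this list turned from 0.0677 to -0.0725 without knockout 429. Adjusted over all genes, G6pc was the 1 gene of all the lists that passed.

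No measured gene of the sphingolipid pathways around Ugcg passed, adjusted over all genes or over its list alone. Of 22 genes of glycosphingolipid synthesis, 15 were higher and 7 lower, with a median difference of 0.0216 (adjusted p = 0.660); the sialyltransferase gene St3gal1 differed by 0.24 (0.0651 without knockout 427 and 0.501 without wildtype 430) and B4galnt1, which makes GM2 and GD2, by 0.10 (0.0345 without knockout 427 and 0.160 without knockout 429). Of 13 genes of glycosphingolipid degradation, 8 were higher and 5 lower (median 0.0257, adjusted p = 0.794), with 0.07 for the saposin precursor Psap and -0.04 for the GM2 activator Gm2a. The mean of this list turned from 0.0254 to -0.0441 without wildtype 430, and it also turned without knockout 429. Ceramide and sphingomyelin metabolism had 15 higher and 13 lower genes (median 0.0243, adjusted p = 0.830), with -0.06 for the ceramide synthase gene Cers2 and 0.17 for the desaturase gene Degs1. The lysosome list had 14 higher and 12 lower members (median 0.0189, adjusted p = 0.838). Without wildtype 430 the mean of the lysosome list turned from 0.0139 to -0.0253 (it also turned without knockout 429) and that of the ceramide list from 0.0130 to -0.00362. Lipid rafts, caveolae and vesicle traffic had 15 higher and 4 lower (median 0.0719, adjusted p = 0.0834).

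Among the lists for hepatocyte function, bile acid synthesis had 13 higher and 4 lower genes (median 0.0599, adjusted p = 0.179), with 0.05 for Slc27a5 and -0.12 for Hsd3b7, and bile and organic anion transport had 8 higher and 11 lower (median -0.0547, adjusted p = 0.493), with -0.08 for the bile acid importer Slc10a1 and -0.20 for Slco1b2. The sign of Slc27a5 turned without knockout 429 (-0.0259). Xenobiotic metabolism had 12 higher and 24 lower genes (median -0.0544, adjusted p = 0.0531), with -0.05 for Cyp2e1 and -0.09 for Cyp3a11. This list passed after quantile normalization (adjusted p = 0.0446), with array quality weights (0.0329), without wildtype 430 (0.00897) and without knockout 429 (0.00198), always with the preset correlation, and over the 12 refits its adjusted p reached 0.269. With all arrays its adjusted p was 0.763 with an estimated correlation and 0.785 by fry. Tight junctions and the canalicular membrane had 10 higher and 8 lower (adjusted p = 0.660), with 0.11 for Gjb2 and -0.11 for Gjb1, the hepatocyte gap junction genes. The clock list had 13 higher and 8 lower (adjusted p = 0.397), with 0.30 for Nfil3 and 0.65 for Bhlhe40. Periportal hepatocyte genes had 10 higher and 3 lower (median 0.0384, adjusted p = 0.0834). The adjusted p was 0.660 for lipoprotein assembly and uptake, 0.830 for cholesterol synthesis, 0.795 for fatty acid and triglyceride synthesis, and 0.838 for fatty acid oxidation and PPAR-alpha targets. It was 0.660 for NRF2 and oxidative stress, and 0.830 for the female-biased and the male-biased liver genes. Leaving out 1 array turned the sign of the mean for bile and organic anion transport (-0.0816 to 0.0170), tight junctions (-0.00926 to 0.0553), cholesterol synthesis (-0.0300 to 0.0809), fatty acid and triglyceride synthesis (-0.0950 to 0.103) and fatty acid oxidation (-0.0272 to 0.130). It also did so for NRF2 (-0.0569 to 0.0112), male-biased (-0.0644 to 0.0381) and female-biased genes (-0.00483 to 0.0870).

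Among markers of other cells and tissues, the cholangiocyte list had 10 higher and 3 lower members (median 0.174, adjusted p = 0.0834), and knockout 429 had the highest list mean, 0.40 above the wildtype mean of its genes. The mean difference of this list, 0.158, was 0.0374 without knockout 429 and 0.239 without knockout 431. The bile duct keratin Krt19 differed by 0.36, with 7.60 in knockout 429 and 6.33 to 6.46 elsewhere, and by -0.0594 without that array; Sox9 differed by 0.04 and by -0.0600 without wildtype 430. Adipose tissue and muscle had 9 higher and 2 lower members (median 0.258, adjusted p = 0.0788), with a list mean of 0.57 in knockout 427 on the same scale. The mean difference of this list, 0.241, was 0.0771 without knockout 427 and 0.357 without knockout 429. Stellate cells and fibrosis had 14 higher and 8 lower (adjusted p = 0.476), with 0.09 for Dcn and -0.11 for Ecm1; its mean of 0.0480 was 0.112 without wildtype 428 and turned to -0.0143 without knockout 429. Kupffer cells and macrophages had 4 higher and 16 lower (median -0.0976, adjusted p = 0.0834). Their list mean was lowest in knockout 431 (-0.34 relative to wildtype) and highest in knockout 429 (0.22), and the difference of -0.0756 was -0.226 without knockout 429 and 0.0547 without knockout 431. The adjusted p was 0.830 for the liver endothelium and for red blood cells, 0.440 for lymphocytes, 0.660 for neutrophils, 0.201 for progenitor and fetal liver genes, 0.115 for the acute phase response and 0.830 for the interferon response. The mean turned sign when 1 array was left out for the interferon (-0.0535 to 0.148), endothelium (-0.0408 to 0.0274) and red blood cell lists (-0.00550 to 0.0492). The mean and the median had opposite signs for the interferon (0.0189 and -0.0184), endothelium (-0.00659 and 0.0181) and female-biased (0.0372 and -0.000651) lists. For fatty acid and triglyceride synthesis both were below 0 (-0.00665 and -0.00618) while camera's direction was up.

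A last comparison asked whether genes beside Ugcg on its chromosome differed more often than other genes. Of the 100 nearest genes with a probe set, 50 on each side, 7 had an unadjusted p under 0.05, against 770 of 15516 other genes (7% against 4.96%, two-sided Fisher's exact test, p = 0.349). None of the 100 and 4 of the others passed the limma adjusted p (Fisher's exact test, p = 1). With dim probe sets left out, 10 of the neighbours had an unadjusted p under 0.05 and the Fisher's exact test passed (p = 0.0294), and the share of neighbours was below that of other genes with 25 genes on each side (2 genes, p = 1) and without knockout 431 (6 genes, p = 1).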

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

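Leaving out wildtype 430 and knockout 427 together was chosen after the data were seen. The 4 called genes kept their direction under all 12 refits but did not pass in all of them: G6pc in 7 (0.87 to 1.05, adjusted p 0.00424 to 0.197), Ndufs5 in 7 (-0.87 to -0.75, 0.00970 to 0.220), Cish in 5 (-1.37 to -1.12, 0.00970 to 0.198) and Rnf145 in 4 (0.78 to 0.93, 0.0201 to 0.262). Because the groups do not overlap for these genes, leaving out arrays could not turn their direction, so the kept direction is no sign of stability. The count of probe sets was 4 with all arrays, 3 after quantile normalization, 4 after median centring or without dim probe sets, 6 with a trend and robust variance, 8 with array weights, 8 without both arrays, and 0 to 4 leaving out each array in turn; leaving out an array also leaves fewer samples. It was 8 at an adjusted p under 0.10, 0 under 0.01 (815 at an unadjusted p under 0.05) and 4 with at least 1.5-fold added. Named genes numbered 9 with trend and robust variance, 8 with weights, 10 without both arrays and 0 to 4 leaving out one array. Lists passed numbered 0 with an estimated correlation, 0 by fry, 3 with quantile normalization, weights or both arrays out, and 2 to 9 leaving out one array (9 without knockout 427). Beyond the pancreas and p53 lists, those that passed were fatty acid and triglyceride synthesis and periportal genes without wildtype 426; acute phase, interferon, periportal, stellate and lipid raft genes without wildtype 428; ER stress, bile transport and xenobiotic genes without wildtype 430; bile acid synthesis, insulin and glucose, acute phase, pericentral, periportal, fetal liver and neutrophil genes without knockout 427; xenobiotic, Kupffer, and adipose and muscle genes without knockout 429; cholangiocyte genes without knockout 431; ER stress and acute phase genes without both arrays; and xenobiotic genes with quantile normalization or weights. The pancreas list, at -0.858 under the estimated correlation and fry, neither of which it passed, ran from -1.27 to -0.0338 leaving out one array and was -0.00706 without both, because wildtype 430 holds its high values. The p53 list, at -0.0965 under both of those tests and passed by neither, ran from -0.137 to -0.0662 leaving out one array and was -0.147 without both. Ugcg ran from -0.154 to 0.0675 leaving out one array. Genes near Ugcg at an unadjusted p under 0.05 numbered 10 without dim probe sets (p = 0.0294, Fisher's exact test), 2 with 25 genes on each side, 15 with 100 (p = 0.101), and 4 to 8 leaving out one array. Leaving out one array, Sox9 ran from -0.0600 to 0.124 (-0.0337 without both), Krt19 from -0.0594 to 0.572 and Slc27a5 from -0.0259 to 0.116. Except where stated, the cause was not tested. Over 764 combinations of a setting and a gene named by the rule, Ugcg apart, 722 kept direction and side of the threshold, 13 newly passed, 25 no longer passed and 4 reversed. Only the 4 called genes could lose a pass, so all 25 losses fell on them. Most of the other genes lay far from the threshold with all arrays, so the 722 do not measure stability. The planned mean over several probe sets of a gene, the removal of probe sets that bind several transcripts and the offsets for linear values were not run, because the table has 1 probe set per gene, none of that kind, and log2 values. No paired analysis was run, because the groups share no replicate numbers. The numbers alternate between wildtype and knockout from 426 to 431, and the labels do not say whether neighbouring numbers form pairs. Signal over background could not be judged for dim genes without detection calls.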

Other observations

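Several genes outside the rule for named genes, chosen after their values were seen, differed by more than 1 on the log2 scale without passing the adjustment over all genes. Cib3, a calcium- and integrin-binding protein gene, read 8.73 to 9.26 on the knockout arrays and 6.95 to 8.13 on the wildtype arrays (1.41, adjusted p = 0.416). Egr1, an immediate early transcription factor, differed by -1.38, and its groups did not overlap. Arrdc3, an arrestin-domain gene, differed by -1.29, and Lpin1, a phosphatidate phosphatase, by -1.26. Egr1 (-2.04), Arrdc3 (-1.75), Lpin1 (-1.59) and the PPAR-alpha target Cyp4a10 (0.93) were among the 10 named genes past the threshold without wildtype 430 and knockout 427. With all arrays Cyp4a10 differed by 0.71, and leaving out one array moved it from 0.30 (without wildtype 430) to 1.34 (without knockout 427). Arrdc3 moved from -1.80 (without knockout 427) to -0.84 (without knockout 429). The lipid elongase gene Elovl6 differed by 0.65, again without overlap.

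Single knockout arrays stood apart in groups of genes, also noticed after the values were seen. Knockout 427 had the highest value of the heat shock genes Hspa1b (11.60, with 9.998 in wildtype 430 as the next highest), Hsph1 (10.80, with 10.17 in wildtype 430) and Dnajb1 (9.80), and the skeletal muscle actin Acta1 read 8.48 there against 6.28 to 6.63 elsewhere. Knockout 429 had the highest Krt19 and Cd24a (7.71), both genes of bile duct cells. Knockout 431 had the highest values of the serum amyloid genes Saa1 (12.75) and Saa2 (9.46).

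The tests of a probe set outside the deletion, of exchanged labels and of fasting were chosen after the values were seen. So were those of both explanations of the pancreas pattern. Those of knockout 427 and of the splits were set before. The STAT5 test was written before its result. It was made for Cish, a called gene, and its bound was scaled from the difference of Cish in these arrays. For Ugcg, which differed by -0.00879 with 7.12 in knockout 427, none of the explanations examined could be excluded. Its mean lay at percentile 51.3 of all probe sets, and without detection calls its signal over background could not be judged. An exchange of 1 wildtype and 1 knockout label stays open, because the probe set does not check the labels. The lowest wildtype array lay 0.116 above the higher of the pair of lower knockout arrays. That gap was within the knockout SD of 0.252 but beyond the wildtype SD of 0.0279. Knockout 427 itself widens the knockout SD, so this comparison cannot decide. A probe set that reads transcript outside the deleted exons may account for the values, and stays untested without probe positions. A knockout 427 that still has Ugcg stays open too: over the 50 genes that best part the other 5 arrays, its median place was 0.457, where 0 is the wildtype and 1 the knockout mean. Held out in the same way, wildtype arrays lay at 0.265, 0.380 and 0.526 and the other knockout arrays at 0.614 and 0.506, so the genotypes are not well parted by this measure.

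The pancreatic genes are lower in the knockout group by a mean of -0.858. A genotype effect is argued against, since the difference without wildtype 430 was -0.0338 (SE 0.0635). Pancreatic tissue taken with the wildtype 430 liver is a candidate explanation: 11 of 11 exocrine genes, from a list fixed before the data were examined, were highest on that array, with a median excess of 2.83 over the mean of the others. Cela1 was above 9.7 on all arrays, so the liver samples gave signal for it throughout.

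For the 4 called genes, 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05; the real split gave 4 probe sets and 4 named genes, the highest other gave 1 of each, and 1 split, the real one, gave as many. At an unadjusted p under 0.05 the other splits gave 423 to 1392 probe sets, 4 of them more than the 815 of the real one. All 10 splits gave at least the 2 lists of the real one, and the highest other gave 14 lists and 1392 probe sets; it set wildtype 426, wildtype 428 and knockout 429 against the rest, with 0 probe sets past the threshold. Lower growth hormone and STAT5 signalling is a hypothesis for Cish. The mean of 4 other STAT5 targets (Igf1 0.13, Igfals 0.18, Onecut1 -0.21, Cyp8b1 -0.04) differed by 0.0129 (SE 0.118, exact permutation p = 0.9). Its lower limit of -0.224 stayed above a bound of -0.323, which was scaled from the difference of Cish itself. The mean of these 4 genes thus gave no sign of a fall that large. How closely they follow Cish is not known from these arrays, and Onecut1 varied widely (SE 0.423), so the hypothesis stays open. A short pulse that moves Cish alone was not tested. A more fasted state of the knockout mice may account for G6pc and stays open. Fasting-raised less fasting-lowered genes differed by 0.199 over 17 genes (SE 0.394, limits of 2 standard errors -0.589 to 0.986, exact permutation p = 0.6). The members at an unadjusted limma p under 0.05 were split. Fasting-raised Pck1 (0.38) and fasting-lowered Pklr (-0.33) moved as fasting would move them. Fasting-raised Ppargc1a (-0.33) and Cpt1a (-0.25) and fasting-lowered Elovl6 (0.65) moved the other way.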
